A study of Mus musculus with 2 samples.

How the data were processed

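The data are spatial transcriptomes (10x Genomics Visium, in which a tissue section lies on a grid of barcoded spots that capture polyadenylated RNA) of 2 sections of mouse pancreatic tumour. Per the labels, the tumours were orthotopic pancreatic ductal adenocarcinomas taken on day 30 from female C57BL/6N mice of genotype WT. The 2 sections, each 10 µm thick and 100 µm apart, were snap frozen, fixed in methanol and stained by immunofluorescence. They form 1 group and are called section 1 and section 2. The labels do not say whether both sections come from the same tumour, although a spacing of 100 µm points to 1 tissue block.

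The deposited matrices hold raw UMI counts (unique molecular identifiers, 1 per captured transcript molecule) per gene and spot under tissue, with 32285 features and no normalisation. The submitters' processing notes give Space Ranger 1.2.0 and the mm10 genome, whereas the matrix header names version 1.2.2. Aligner settings are not given in the sources used here. A position table places each spot on a grid of 4992 positions and marks which lie under tissue. Gene symbols that occur more than once (40) were kept apart by Ensembl identifier. Chromosome positions come from the GENCODE vM21 annotation of GRCm38 (mm10), which holds 32158 of the 32285 identifiers. Image scale factors were not used, and neither were any microscope images.

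Spots differ in depth, so for comparisons that depend on detecting a transcript each spot was thinned at random without replacement to 3000 UMIs, and shallower spots were left out (929 in section 1, 650 in section 2). Levels are given in CPM, the field's usual scaling of a gene's UMIs to a common total, from UMIs summed over the spots concerned. The 95% confidence intervals of shares of spots are exact Clopper-Pearson intervals and, like every interval on counts here, cover counting error only. Total UMIs were 29517210 in section 1 and 36892558 in section 2.

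Spots were compared in 2 ways. In the first, Il1b-positive spots had at least 1 Il1b UMI after thinning and the other spots had 0, and Il1b itself was removed from the test. In the second, rim spots lay at a hexagonal grid distance of 1 or 2 from tissue-free ground (patches of at least 20 positions, with the frame of the capture area not counted as a border) and interior spots at a distance of at least 6, with all UMIs used. Counts were summed per section and class, which gives 4 summed libraries per comparison and 1 residual degree of freedom. Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR's quasi-likelihood test with the section as a block, at a Benjamini-Hochberg adjusted p of 0.05. Fold changes over both sections are log2 values from the edgeR fit. Their standard error was worked back from the fold change and the test's F statistic. Fold changes of single sections are log2 ratios of scaled counts with a prior count of 2, so for sparse genes they can lie off the joint value. In the Il1b comparison edgeR estimated infinite prior degrees of freedom, so that all genes shared 1 trend of spread. In the rim comparison the estimate was 41.1.

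In each comparison 13 genes were always named: Il1b, Il1a, Il1r1, Il1rn, Ptgs2, Tnf, Cxcl1, Cxcl2, Spp1, Folr2, C1qa, Vegfa and Slc2a1, where tested. The rule added the 6 largest rises and 6 largest falls among genes that passed, had a mean of at least 20 CPM and moved the same way in both sections, and up to 4 members of each list with the smallest p. The text gives examples of the list members, and 1 macrophage gene at the rim is not reported here. The 28 disjoint lists hold 317 genes and are named for Il1b macrophages, IL-1 response, neutrophils, macrophages in general, C1q and Folr2 macrophages, Spp1 macrophages, MHC class II and dendritic cells, interferon response, T and NK cells, B and plasma cells, fibroblasts, myofibroblast-type fibroblasts, inflammatory-type fibroblasts, endothelium, pericytes, tumour epithelium, classical epithelium, basal and mesenchymal genes, acinar cells, endocrine cells, mesothelium, adipocytes, skeletal muscle, red blood cells, mast cells, hypoxia and glycolysis, proliferation, and immediate early and stress genes. These lists, the naming rule, the tests and most of the other settings tried were chosen before the data were examined. For each list the number of members called is given over all genes tested and adjusted over the list alone. The median log2 fold change of a list was ranked against 10000 random lists of the same size matched on mean level. With 1 residual degree of freedom no correlation between genes could be estimated for a set test.

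List scores per spot are the mean over detected members of the z-scored log2 of counts per 10000 plus 1, from thinned counts. Co-location is the Pearson correlation of 2 list scores across the spots of a section, ranked against 1000 random lists matched on level that replaced the second list. For distance, spots were grouped by grid steps from the nearest spot with at least 2 thinned Il1b UMIs. Regions came from Leiden clustering of both sections together, on 2000 variable genes without the lists' genes, centred by section, with 20 principal components, 15 neighbours and a resolution of 0.5. The leading genes of a region are the 6 with the largest fold against all other spots among those of at least 50 CPM in the region in both sections. Moran's I, a measure of how alike neighbouring values are, was computed over the 6 neighbours of each spot for genes seen in at least 5% of spots in both sections, with shuffled positions as reference. Spots are not replicates, so no p-value was taken from spots.

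The tests were tried on simulated counts with 200 genes drawn to change. In the Il1b design, edgeR recovered 31.8% of genes changed by 1.5-fold, 62.1% at 2-fold and 84.8% at 4-fold, with 4 false calls. DESeq2 recovered 4.5%, 21.2% and 71.2% with 0 false calls, and limma voom 28.8%, 59.1% and 83.3% with 8. In the rim design edgeR recovered 63.6%, 83.6% and 93.7% with 6 false calls, DESeq2 25.8%, 50.7% and 77.8% with 0, and limma voom 54.5%, 80.6% and 93.7% with 18. With no gene changed, edgeR made 0 calls among 11785 genes in the Il1b design and 0 among 13287 in the rim design. All simulated counts were drawn with the 1 dispersion that edgeR had fitted to all genes, so few false calls were built in. In the real data, 20 random choices of as many spots in place of the Il1b-positive ones called from 0 to 12 genes.

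The other settings chosen at that time were DESeq2 size factors, no filter on low counts, DESeq2 and limma voom, no section block, each section alone, other thinning depths, other thresholds for Il1b, subsets of spots, other rim and interior limits, rank and partial correlations, other sources for distance, and other clustering resolutions and gene sets. Settings added after the data were seen were negative spots matched on depth or on region, rim spots without muscle transcripts, scores of neighbouring spots, spots outside region 3, and the Il1b-macrophage list without Il1rn and Thbs1. Work was done with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.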

Results

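The expression of 32285 genes was mapped in 2 tissue sections of mouse pancreatic ductal adenocarcinoma, grown orthotopically and taken on day 30. Both sections belong to 1 group, so no treatment or time was compared. The series title concerns macrophages that carry IL-1β and inflammation in this cancer, and the comparisons therefore ask which genes accompany Il1b transcripts (the gene of IL-1β, a cytokine that starts inflammation), and where in the tumour they lie. Every adjusted p below comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It reflects counting error and a spread between sections that was shared by all genes in the Il1b comparison and largely so at the rim. A small p therefore does not show that a gene's values in the 2 sections agree. The spacing of 100 µm between the sections points to 1 tumour, which the labels do not state, so the p-values may be too small.

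Section 1 had 3444 spots under tissue with 29517210 UMIs in all, and section 2 had 3822 spots with 36892558 UMIs. The median spot held 7324 UMIs and 3157 genes in section 1, and 8098 UMIs and 3386.5 genes in section 2. Single spots ranged from 66 to 27971 UMIs and from 18 to 31445 UMIs. Mitochondrial transcripts took 4.55% and 4.25% of the UMIs. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, GRCm38) was sparse, with 686 UMIs (23.2 CPM) in section 1 and 871 UMIs (23.6 CPM) in section 2. At full depth it was seen in 14.1% of spots of section 1 (95% interval 12.99 to 15.3%) and 16.8% of section 2 (15.6 to 18.0%). With every spot thinned to 3000 UMIs, it was seen in 179 of 2515 spots, or 7.12% (6.14 to 8.19%), and in 255 of 3172 spots, or 8.04% (7.12 to 9.04%). Il1rn, the natural antagonist of the IL-1 receptor, was far more abundant, at 255 and 287 CPM, whereas Il1a had 84 and 59 UMIs and the receptor gene Il1r1 470 and 603 UMIs. Normal pancreas left little trace. The acinar list summed to 3.90 and 4.45 CPM and the endocrine list to 15.0 and 10.8 CPM, against 8198 and 7472 CPM for the tumour epithelium list and 5186 and 7159 CPM for the fibroblast list.

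The 2 sections had closely similar profiles. Across 13456 genes with at least 20 UMIs in both, the log2 ratio of section 2 over section 1 had an SD of 0.28, and 99 genes differed by more than 2-fold. Pearson's r of their log2 levels was 0.993, across genes, which are not independent replicates. Among the largest differences, muscle genes were higher in section 2, such as Myh4 (log2 ratio 2.04) and Ttn (1.95), and so were Tgfb1 (1.53) and the acute phase gene Saa3, at 62.4 CPM in section 1 and 126 CPM in section 2. Genes lower in section 2 included Hist1h2ap (-1.80), Gm10076 (-1.62) and Gstp1 (-1.60), whose reads are hard to assign because near-identical copies exist in the genome.

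Clustering of the spots gave 7 regions, all present in both sections. Region 1, led by Cym, Sult1c2, Gsta4, D630003M21Rik, Sptssb and Dmbt1, held 38.7% of the spots of section 1 and 30.0% of those of section 2, and its spots were the deepest (medians of 15909.5 and 17609 UMIs). Region 2, led by Rgs5, Gm26917, Mmp14, Sparcl1, Birc5 and Psmd13, held 24.8% and 27.4%, with medians of 6132 and 7565 UMIs. Region 3, led by Serpinb2, Gipr, Mt2, Cryab, Saa3 and Marco, held 10.8% and 13.9%, with medians of 7496.5 and 6013 UMIs. It lay nearer the tissue border, at a median of 4 and 5 grid steps against 9 and 10 for region 2. Region 4, led by Ccdc88a, Hba-a2, Gcc2, Hba-a1, Hbb-bs and Cmip, held 8.07% and 12.5%, and the shares of Hba-a1 and Hba-a2 are uncertain because the 2 genes share reads. Region 5, led by Lrrc15, Nrep, Postn, Il11, Igfbp3 and Mcpt8, held 9.78% and 7.82%. Region 6, led by Sfrp1, Ctla2a, Gpx3, Cpxm1, Ccn5 and Mmp3, held 5.89% and 4.86% and had mean fibroblast scores of 0.70 and 0.58. Region 7, led by the muscle genes Acta1, Ttn, Tnnt3, Ckm, Myh4 and Tnnc2, held 1.95% and 3.56%.

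**Figure D1:**
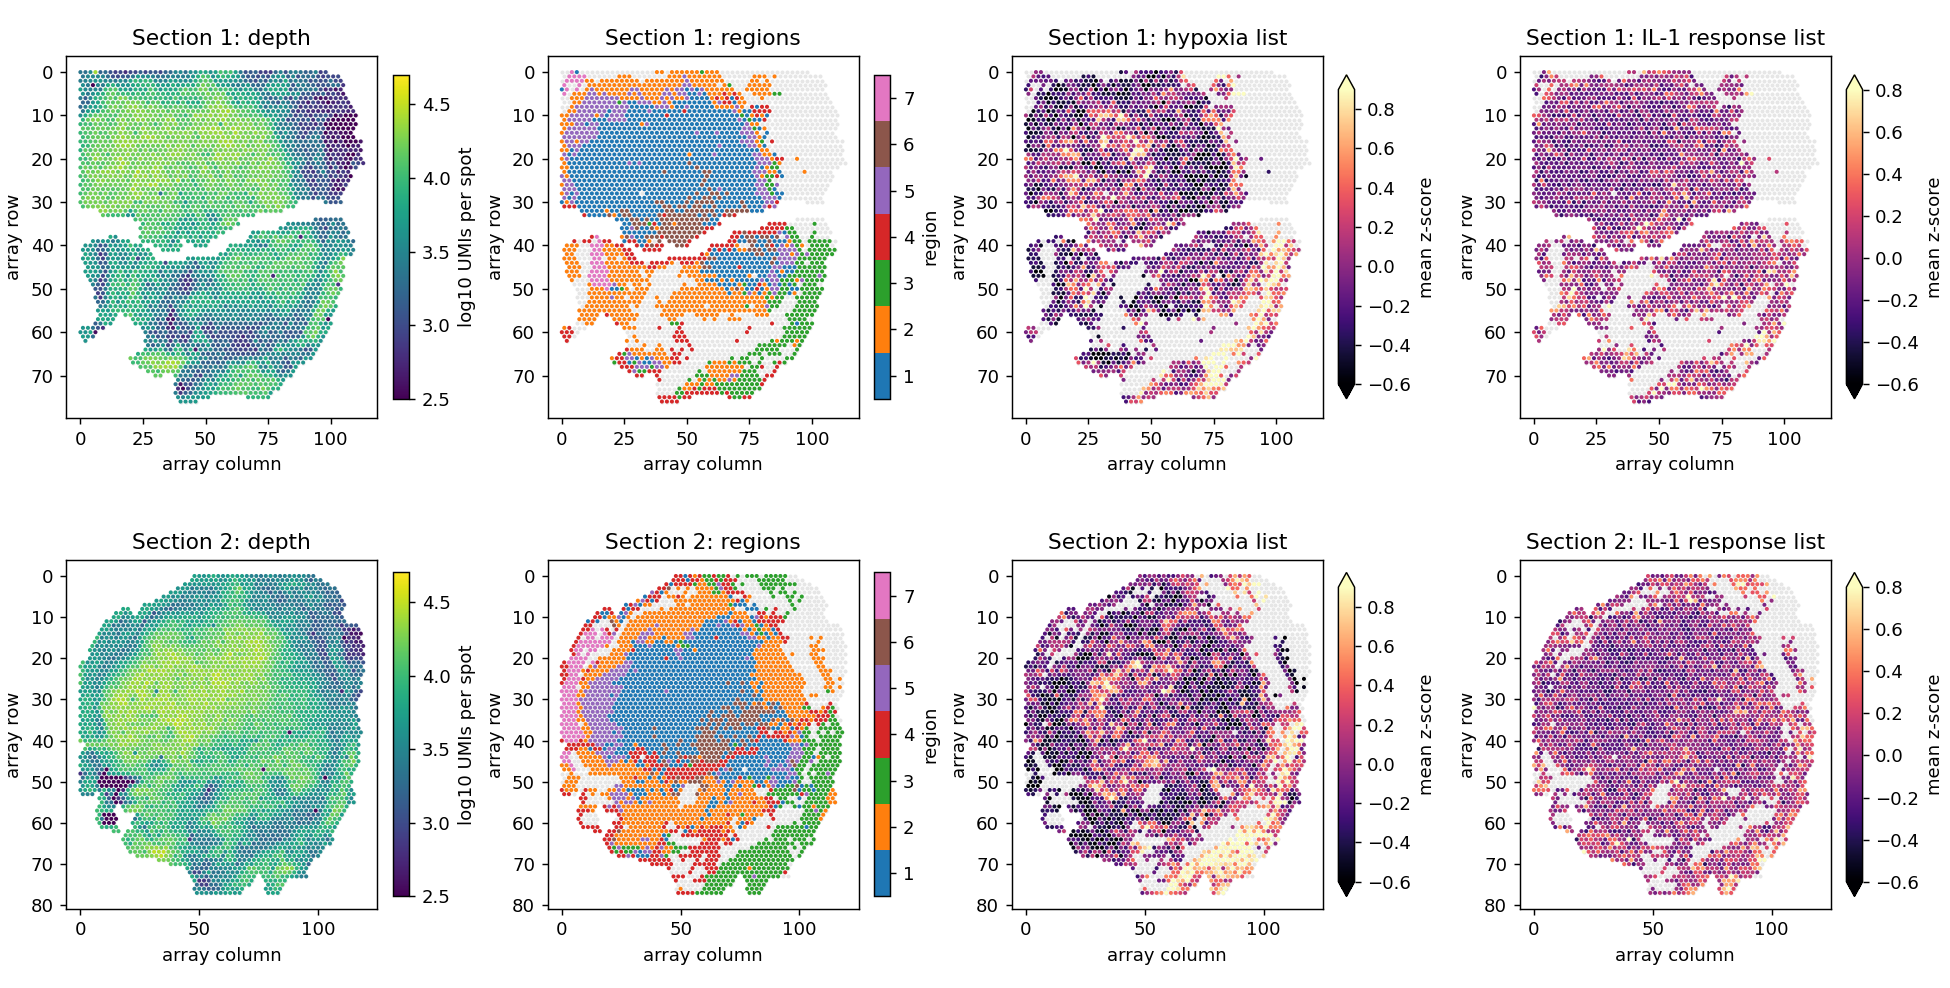
Maps of the 2 sections (array column against array row) coloured by UMIs per spot, by region, by the score of the hypoxia list and by the score of the IL-1 response list, with spots under 3000 UMIs in grey. Region 3 has a mean hypoxia score of 0.57 in both sections.

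Region 3 held the highest levels of Cxcl2, Ptgs2 and Saa3 of all 7 regions in both sections, while Il1b itself was at a similar level in region 2. Cxcl2, a chemokine that draws neutrophils, was at 39.2 and 54.3 CPM in region 3, against 4.82 and 8.06 CPM in region 2 and 2.40 and 3.86 CPM in region 1. Ptgs2, the inducible enzyme of prostaglandin synthesis, was at 219 and 369 CPM in region 3, 71.7 and 81.0 CPM in region 2, and 14.7 and 34.0 CPM in region 1. Saa3 was at 254 and 846 CPM in region 3, 55.6 and 143 CPM in region 2, and 4.79 and 17.5 CPM in region 1. Region 7 came next after region 3, at 190 and 192 CPM on 49 and 113 spots, so the lead of region 3 in section 1 is uncertain. The hypoxia gene Vegfa was at 482 and 537 CPM in region 3 and 175 and 176 CPM in region 2. Il1b was at 42.9 and 43.0 CPM in region 3, 45.5 and 42.6 CPM in region 2, and 10.3 and 15.1 CPM in region 1. In thinned spots Il1b was seen in 10.7% (7.26 to 15.0%) and 12.2% (9.31 to 15.6%) of region 3, in 11.4% (9.01 to 14.2%) and 10.9% (8.95 to 13.2%) of region 2, and in 2.98% (2.00 to 4.25%) and 4.21% (3.03 to 5.69%) of region 1, which serves as the background since its share was the lowest. Regions 4, 5, 6 and 7 had Il1b at 31.2 and 31.9, 27.1 and 17.5, 33.8 and 32.5, and 13.6 and 14.7 CPM.

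**Figure D2:**
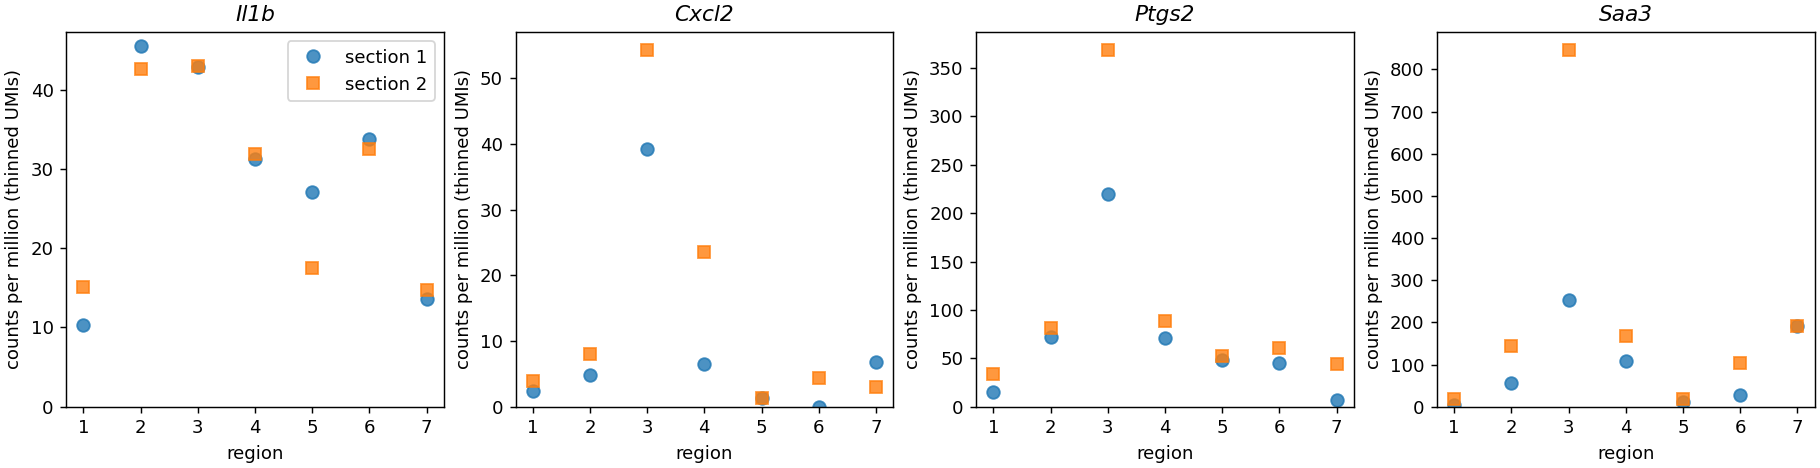
Levels of Il1b, Cxcl2, Ptgs2 and Saa3 (CPM of thinned counts, vertical axes) in each of the 7 regions, with 1 point per section. Il1b reaches 42.9 and 43.0 CPM in region 3 and 45.5 and 42.6 CPM in region 2, while Cxcl2, Ptgs2 and Saa3 are highest in region 3 in both sections.

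Region membership accounted for 83.4% of the variance between spots of the muscle score, 30.7% ± 6.05 of the hypoxia score (SD, n = 2), 24.97% of the inflammatory-type fibroblast score and 18.7% of the fibroblast score. The share of the fibroblast score was 7.15% with regions clustered at resolution 0.3 and 27.7% with the genes of the lists kept in the clustering. For the IL-1 response list the share was 12.8% ± 1.16, for the Il1b-macrophage list 8.17% ± 0.44 and for T and NK cells 0.215% (1.11% with section 2 clustered alone and 0.103% with section 1 alone). Region 3 exceeded the other spots by 0.65 in the hypoxia score, by 0.18 ± 0.013 in the IL-1 response score and by 0.21 ± 0.004 in the Il1b-macrophage score, and its tumour epithelium score was lower (difference -0.22). Its general macrophage score (-0.0 and 0.001) and its C1q and Folr2 macrophage score (-0.009 and -0.012) lay close to the section mean. Its neutrophil score (0.102 and 0.083) was the highest of all regions. The excess in the Il1b-macrophage score was thus not one in macrophage genes in general. When section 1 was clustered alone, the region highest in hypoxia genes, of whose 400 spots 213 belong to region 3, exceeded the other spots by 0.123 in the IL-1 response score and by 0.381 in the hypoxia score. Its tumour epithelium difference was -0.109, and the hypoxia share of variance was 12.4%.

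Spots with Il1b transcripts were rich in macrophage and antigen presentation genes and poor in epithelial ones. C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), a complement gene of macrophages, rose from 244 to 599.6 CPM in section 1 and from 327 to 595 CPM in section 2, a log2 fold change of 1.04 ± 0.07 (SE, 2 of 2 sections higher, adjusted p = 1e-44 by edgeR's quasi-likelihood test). Cd74, the invariant chain of MHC class II, rose by 0.91 ± 0.08 (2 of 2 sections, adjusted p = 1.57e-27). Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) rose by 1.57 ± 0.32, from 5.99 to 22.4 CPM and from 12.6 to 34.0 CPM (2 of 2 sections, adjusted p = 0.000104). Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227) rose by 0.73 ± 0.13, from 56.7 to 110 CPM and from 99.2 to 153 CPM (2 of 2 sections, adjusted p = 8.34e-06). Lgals4, a lectin of gut-type epithelium, fell by 0.48 (SE 0.06) in the positive spots of both sections (adjusted p = 1.29e-13). Of 12007 genes tested, 257 were higher and 118 lower in positive spots, and 374 of these 375 moved the same way in both sections.

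The largest rises beyond 20 CPM, each in both sections, were those of Hp, the haemoglobin scavenger haptoglobin (1.53 ± 0.30), the smooth muscle gene Cnn1 (1.44), Cmtm7 (1.44), H2-DMa (1.31), the chemokine gene Ccl24 (1.26) and the leukocyte actin regulator Coro1a (1.25). The largest falls were those of the fast muscle myosin Myh4 (-1.52), Slc35a1 (-1.17; -2.13 in section 1 and -0.68 in section 2), the DNA repair gene Xpc (-1.09), Pcgf2 (-1.07), Zfp57 (-0.96; -0.38 and -1.45) and the troponin gene Tnnc2 (-0.95; -1.90 and -0.64). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) rose by 1.14 ± 0.10, but almost wholly through section 2, at 0.21 in section 1 and 1.36 in section 2, and likewise Arg1, which consumes arginine, at 0.19 and 1.04. With the 18 and 24 spots that held at least 2 Il1b UMIs as the positive class, the fold changes of Saa3 (-0.68), Hp (-0.65), Cmtm7 (-1.01), C3 (-0.33) and Il33 (-0.13) had the opposite sign and did not pass, in a setting where the median of all genes was -0.245. Other genes of the IL-1 axis did not pass the test: Il1a 0.90, Il1r1 0.41, Il1rn 0.15, Tnf 0.85 and Cxcl1 0.32, with adjusted p from 0.408 for Tnf to 0.728 for Cxcl1. Neither did Spp1 (-0.03), Vegfa (-0.05) and Slc2a1 (-0.04).

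Among the fixed lists, 4 of 14 tested Il1b-macrophage genes rose (6 adjusted over the list alone), with a median log2 fold change of 0.83 and Cxcl2, Thbs1 (0.72), Clec4d (1.27) and Ccl4 (1.15) as members. Thbs1 correlated more with the fibroblast score (0.28 and 0.265) than with the general macrophage score (0.191 and 0.17). Of 25 IL-1 response genes 6 rose (7 adjusted over the list alone), with a median of 0.31, which was 0.15 in section 1 and 0.36 in section 2. It was 0.189 and 0.19 with negative spots matched on depth and on region. Saa3, Mmp13 (0.58), Il33 (0.53) and Ptgs2 were the members of smallest p. Of 12 general macrophage genes 6 rose (8 adjusted over the list alone), including Lyz2 (0.82), Ctss (1.06) and Tyrobp (1.05), with a median of 0.63. Of 8 C1q and Folr2 macrophage genes 5 rose, C1qa, C1qb (0.55), C1qc (0.82), Pf4 (0.92) and Mrc1 (0.55), with 7 up and Selenop (-0.22) down adjusted over the list alone, and all 4 tested MHC class II genes rose (4 adjusted over the list alone), including H2-Ab1 (0.98) and H2-Eb1 (1.18). Of 8 neutrophil genes 2 rose (4 adjusted over the list alone), Csf3r (1.71) and Mmp9 (0.87). Mmp9, however, correlated with the general macrophage score (0.198 and 0.135) and not with the neutrophil score (-0.009 and 0.012). Of 11 Spp1-macrophage genes 3 rose (4 adjusted over the list alone), Mmp12 (0.92), Fabp5 (0.75) and Arg1. Among the stromal lists, the genes that rose were 6 of 12 fibroblast genes (6 adjusted over the list alone), such as Col1a1 (0.39), 4 of 12 myofibroblast-type genes (6), such as Tnc (0.64; 0.95 in section 1 and 0.39 in section 2), 1 of 10 inflammatory-type fibroblast genes (2), C3 (0.42; 0.67 and 0.25), and 1 of 12 endothelial genes (2), Flt1 (0.66). Of 10 tumour epithelium genes 4 fell (7 adjusted over the list alone), such as Krt19 (-0.23) and Muc1 (-0.30; -0.46 and -0.18), and of 7 classical epithelium genes 3 fell (3), such as Ctse (-0.32). Of 6 muscle genes 4 fell (5 adjusted over the list alone), including Acta1 (-0.71; -1.28 in section 1 and -0.49 in section 2), but with negative spots drawn from the same regions the list's median was 0.041, with Acta1 at 0.02 and Tnnt3 at 0.08. Of 3 mesothelial genes Msln fell (-0.19; 1 adjusted over the list alone), although the list's median was 0.13.

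By edgeR, 0 members passed over all genes in the lists for hypoxia (16 tested), proliferation (12), interferon (11), immediate early and stress genes (10), basal and mesenchymal genes (9), pericytes (6), red blood cells (5), T and NK cells (4) and adipocytes (3). Adjusted over the list alone, 2 proliferation genes and 1 immediate early gene were higher, 1 adipocyte gene was lower, and the counts of the other lists stayed at 0. At an unadjusted p under 0.05 these lists held 2 lower hypoxia genes, 4 higher proliferation genes, 1 higher and 1 lower immediate early gene, 1 lower adipocyte gene, and 1 higher gene each for the remaining 5. DESeq2 called 0 members in all 9 lists, and limma voom called 1 higher immediate early gene and 1 lower adipocyte gene. The hypoxia median was -0.03, the proliferation median 0.23 and the adipocyte median -1.33, the latter on counts of 0 in positive spots of section 1. Lists with fewer than 3 tested genes have no median. For these, Igkc (0.19), Igha (0.97), Cela1 (0.60), Ttr (-1.34), Mcpt4 (-0.50) and Kit (0.89) did not pass. The medians of 15 of the 24 lists that could be ranked lay outside 95% of random lists of like level.

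**Figure D3:**
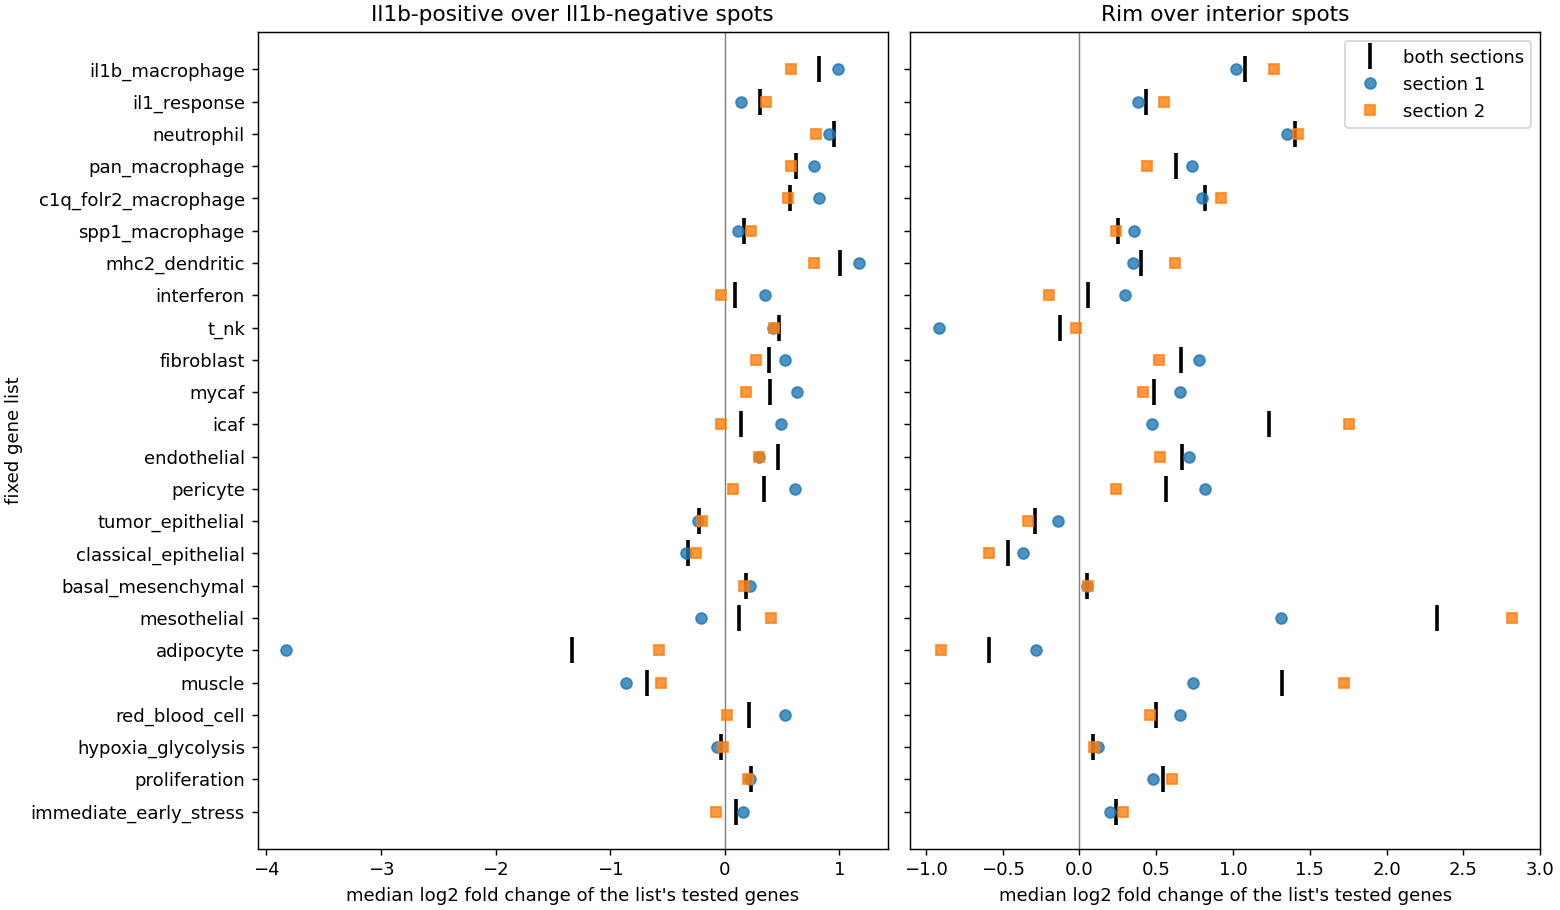
Median log2 fold change of each fixed list for Il1b-positive against negative spots and for rim against interior spots, with a bar mark for the fit of both sections and 1 point for each section. The macrophage, MHC class II and neutrophil lists lie above 0 in both comparisons and the 2 epithelial lists below 0.

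Positive spots were shallower than negative ones before thinning, at medians of 8592 against 10980 UMIs in section 1 and 8748 against 10197 UMIs in section 2, and had more of the ribosomal RNA transcript Gm42418, at 1.61% against 1.42% and 1.91% against 1.77%. The counts of higher and lower genes depended on the processing: 1101 and 655 without thinning, 3 and 0 with thinning to 1500 UMIs (377 and 432 at an unadjusted p under 0.05), 161 and 63 with negative spots matched on depth, 114 and 23 with negative spots matched on region, 48 and 7 with DESeq2, and 12 and 0 without the section block (552 and 373 at an unadjusted p under 0.05). Limma voom called 382 and 128.

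At the rim of the tissue, most fibroblast, endothelial, general macrophage and neutrophil genes tested were higher than in the interior, and so was Il1b. Slpi (ENSMUSG00000017002, chromosome 2, 164354070 to 164389095), an inhibitor of neutrophil elastase, rose from 2.92 to 40.8 CPM in section 1 and from 6.37 to 102 CPM in section 2, a log2 fold change of 3.92 ± 0.15 (2 of 2 sections, adjusted p = 1.23e-23 by edgeR's quasi-likelihood test). Saa3 rose by 3.14 ± 0.13, from 23.8 to 127.3 CPM and from 52.9 to 667 CPM (2 of 2 sections, at 2.40 and 3.65, adjusted p = 1.19e-22). Il1b rose by 0.97 ± 0.14, from 18.8 to 29.8 CPM and from 19.5 to 47.7 CPM (2 of 2 sections, at 0.65 and 1.28, adjusted p = 1.16e-06). Cym (ENSMUSG00000046213, chromosome 3, 107211293 to 107221732), the milk-clotting protease chymosin, fell by 1.19 (SE 0.09, lower in 2 of 2 sections, adjusted p = 4.54e-14). Of 13529 genes tested, 2053 were higher and 1519 lower at the rim, 3563 of these 3572 in the same direction in both sections, on 575 rim and 2148 interior spots of section 1 and 377 and 2916 of section 2.

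The other large rises were those of Tnfaip6 (3.07), Adgrd1 (2.92), the macrophage scavenger receptor Marco (2.91) and the integrin Itgam (2.41), and the other large falls those of Mcpt4 (-1.22), Sult1c2 (-1.16), Ugt2b35 (-0.98), Fxyd3 (-0.97) and Dgat2 (-0.96). Mcpt4 belongs to a family of proteases similar in sequence, so that its reads are uncertain. Ptgs2 rose by 1.2 ± 0.09 (2 of 2 sections, adjusted p = 6.49e-14) and C1qa by 0.90. Cxcl1 rose by 1.003, at 0.63 in section 1 and 1.30 in section 2. Il1r1 rose by 0.97, at 0.51 in section 1 and 1.42 in section 2. Cxcl2 rose by 2.04 ± 0.21 (2 of 2 sections, adjusted p = 2.2e-10), but by 0.95 with spots thinned to 3000 UMIs, where it no longer passed. Spp1 fell by 0.17 (lower in 2 of 2 sections, adjusted p = 0.0279). Tnf (0.61), Il1rn (-0.16), Folr2 (0.56), Il1a (-0.10), Vegfa (0.02) and Slc2a1 (-0.01) did not pass.

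Of 16 Il1b-macrophage genes 11 rose at the rim (14 up and 1 down adjusted over the list alone), with a median log2 fold change of 1.08 and with Thbs1 (1.19) and Clec4d (1.67) as examples. Of 26 IL-1 response genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), including Il33 (1.41) and Ccl2 (2.01), with a median of 0.44. Of 10 neutrophil genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), including S100a8 (1.30) and S100a9 (1.36). Of 12 general macrophage genes 9 rose and 1 fell (10 and 1), including Ctss (1.12), of 11 C1q and Folr2 macrophage genes 8 rose and 1 fell (8 and 1), including Gas6 (1.55), of 11 Spp1-macrophage genes 5 rose and 1 fell (6 and 1), including Arg1 (1.78) and Trem2 (1.26), and of 6 MHC class II and dendritic genes 4 rose (4), including H2-Ab1 (0.66), the counts in brackets being adjusted over the list alone here and below. Of 4 B and plasma cell genes 3 rose (3), Igkc (2.46), Igha (4.36; 2.45 in section 1 and 5.29 in section 2) and Jchain (2.38; 1.16 and 2.56). Of 12 fibroblast genes 8 rose (10 up, 1 down), including Dcn (1.81), of 12 myofibroblast-type genes 8 rose and 2 fell (8 and 2), including Tagln (1.68), and of 11 inflammatory-type fibroblast genes 8 rose (8), including Il6 (3.48) and the chemokine gene Cxcl12 (2.03). Of 12 endothelial genes 9 rose (9), including Plvap (1.60), and of 6 pericyte genes 2 rose (3), Rgs5 (1.58) and Abcc9 (0.68). Of 12 proliferation genes 11 rose (11), including Top2a (0.69). The falls within rising lists, named after their values were seen, were those of Lcn2 (-0.96; -0.71 and -1.49) among IL-1 response genes, Mxd1 (-0.39; -0.18 and -0.75) among neutrophil genes, Cd14 (-0.24), Selenop (-0.54), Postn (-0.83) and Lrrc15 (-0.35). Of 16 hypoxia genes 6 rose, such as Egln3 (0.67), and 1 fell (6 and 2), Car9 (-0.41), and of 10 immediate early and stress genes 4 rose and 1 fell (5 and 1), with Fos (1.44) among the former and Ddit3 (-0.52) the latter.

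Of 10 tumour epithelium genes 7 fell at the rim (7 adjusted over the list alone), including Spint2 (-0.50) and Cdh1 (-0.34; -0.09 in section 1 and -0.62 in section 2), and of 9 classical epithelium genes 5 fell (6), including Hnf4a (-0.77). Of 9 basal and mesenchymal genes 4 rose, such as Zeb2 (1.37), and Hmga2 (-0.20) fell (4 and 2). Of 6 muscle genes 6 rose (6), including Myh4 (1.73; 0.90 in section 1 and 2.08 in section 2), and muscle transcripts were seen in 20.5% of rim and 8.43% of interior spots of section 1 and in 28.6% and 17.6% of section 2. Of 4 mesothelial genes Wt1 (2.13), Upk3b (2.52; 0.61 and 3.45) and Upk1b (at 1.57 and 3.94 CPM at the rim) rose and Msln (-0.21) fell (3 and 1), and of 3 adipocyte genes Car3 (1.99; 1.09 and 2.48) rose and Plin4 (-1.07) and Cidec (-0.59; -0.29 and -1.17) fell (1 and 2). The adipocyte list's median was -0.59, and 1.94 with no filter on low counts. Of 5 red blood cell genes 4 rose (4), including Hbb-bs (0.58), while Hba-a2 (0.43) was at -0.21 in thinned spots. Of 12 interferon genes Oasl2 (0.47) rose and Ifit3 (-0.84; -0.44 and -1.43) fell over all genes, with 0 adjusted over the list alone, where edgeR gave 1 up and 1 down at an unadjusted p under 0.05, DESeq2 0 and limma voom 1 up. Of 8 T and NK cell genes Gzma (-2.12) fell (1). In the lists with fewer than 3 tested genes, Ttr fell (-1.13), and Cela1 (0.52) and Kit (0.39) did not pass. The medians of 20 of 25 lists lay outside 95% of random lists of like level.

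Rim spots were shallower than interior ones, at medians of 5564 against 9123 UMIs in section 1 and 4902 against 9878 UMIs in section 2, and held more Gm42418, at 2.14% against 1.06% and 2.70% against 1.39%. With spots thinned to 3000 UMIs 811 genes were higher and 423 lower, with a rim of distance 1 the counts were 1241 and 852, without spots holding muscle transcripts 963 were lower, DESeq2 called 704 and 239, limma voom called 2198 and 1292, and without the section block edgeR called 0 and 0 (1613 and 911 at an unadjusted p under 0.05).

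Across spots, in the first of 16 pairs of lists, the Il1b-macrophage score went with the IL-1 response score, at a Pearson correlation of 0.181 in section 1 and 0.181 in section 2, where the highest 2.5% of random lists of like level began at 0.0609 and 0.0474. It also went with the scores of Spp1 macrophages (0.214 and 0.164), neutrophils (0.178 and 0.148), C1q and Folr2 macrophages (0.155 and 0.158), macrophages in general (0.156 and 0.154), hypoxia (0.119 and 0.115) and fibroblasts (0.127 and 0.0895), and weakly with the endothelial score (0.0684 and 0.0476). Against the tumour epithelium score it was negative (-0.179 and -0.195), and so was the IL-1 response score (-0.170 and -0.204), where the value of section 1 lay within 95% of random lists. The IL-1 response score correlated with the fibroblast score at 0.161 and 0.160 and with the hypoxia score at 0.0986 and 0.122, but at 0.022 and 0.0571 without thinning. With thinning to 1500 UMIs, the correlation of the Il1b-macrophage score in sections 1 and 2 was 0.0456 and 0.127 with neutrophils, 0.0901 and 0.0887 with macrophages in general, 0.104 and 0.0383 with fibroblasts and 0.041 and 0.0144 with the endothelial score. Outside region 3, the mean correlation with hypoxia was -0.02 for the Il1b-macrophage score and -0.05 for the IL-1 response score. There the Il1b-macrophage score correlated with the Spp1 macrophage score at 0.178 and 0.0776 and with the endothelial score at 0.128 and 0.1003. Spp1 itself correlated negatively with the general macrophage score (-0.151 and -0.148), so the Spp1-macrophage list may follow other cells too. Without Il1rn and Thbs1, the correlation of the Il1b-macrophage and fibroblast scores was 0.0781 and 0.0458. Given the tumour epithelium and macrophage scores, the mean correlation of the Il1b-macrophage score fell to 0.0786 with the C1q and Folr2 macrophage score, to 0.0202 with the fibroblast score (0.0408 in section 1 and -0.0004 in section 2) and to -0.0026 with the endothelial score, and that of the IL-1 response and fibroblast scores to 0.085.

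The IL-1 response score declined with distance from spots that held at least 2 Il1b UMIs in section 1, and less regularly in section 2. In section 1 the 18 source spots had a mean score of 0.0873, spots 1 step away 0.0725, 2 steps 0.0577, 3 steps 0.0334, and those at 4 steps or more -0.01. In section 2 the 24 source spots had a mean of 0.173, followed by 0.0192, 0.0301, -0.0142 and -0.0034. The difference between spots 1 step away and those at 4 steps or more was 0.0821 in section 1 and 0.0226 in section 2. From spots with at least 1 Il1b UMI, that difference was 0.0813 and 0.0761. Free RNA that spreads sideways before capture can raise neighbouring spots in this assay, which these distances do not separate from expression.

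**Figure D4:**
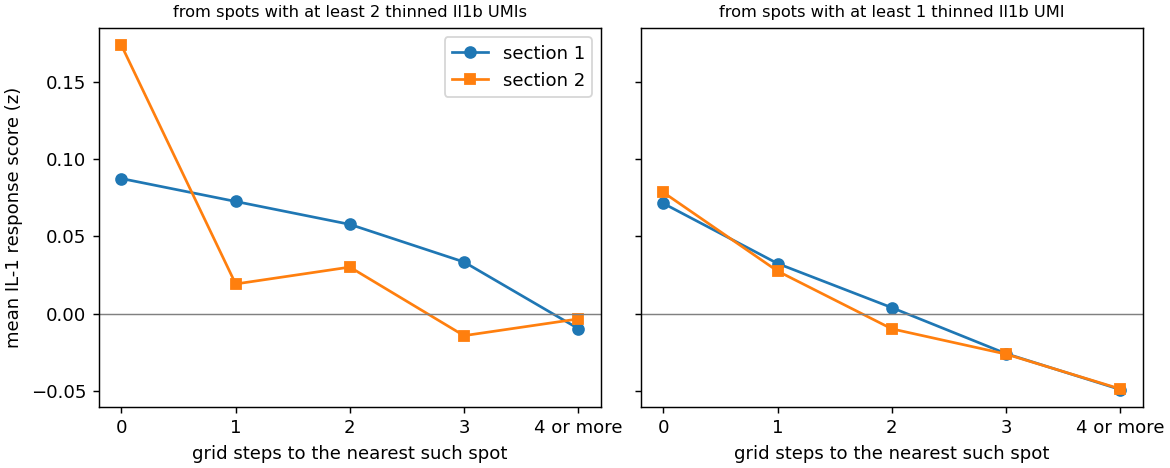
Mean IL-1 response score (vertical axis, score units) by grid steps from the nearest source spot (horizontal axis), for sources with at least 2 and at least 1 thinned Il1b UMIs, with 1 line per section. With sources of at least 1 UMI the score at 1 step exceeds that at 4 steps or more by 0.0813 in section 1 and 0.0761 in section 2.

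The transcripts most patterned in space were led by a muscle actin and included 3 mitochondrial genes. By mean Moran's I over both sections the first 10 of 7562 genes were Acta1 (0.753), mt-Co1 (0.620), the secreted chaperone Clu (0.594), Gm42418 (0.528), Actb (0.501), S100a6 (0.5002), Timp1 (0.499), mt-Co3 (0.462), mt-Atp6 (0.447) and the metallothionein Mt2 (0.431). Il1b reached 0.0351 in section 1 and 0.0443 in section 2, above 89.5% of genes by its mean, while the highest value with shuffled positions was 0.0488 and 0.0375. At full depth its mean was 0.107. In both sections 575 genes exceeded the shuffled maximum. Across genes, which are not independent, Spearman's rho between the sections was 0.431 and Pearson's r 0.893.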

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

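Spots with fewer than 3000 UMIs, which the thinned comparisons leave out and of which the rim comparison uses a part, were looked at only after the other results had been seen, and no test was run on them. In these spots Saa3 stood at 617 CPM in section 1 and 817 CPM in section 2, against 34.1 and 101 CPM in deeper spots. Ptgs2 stood at 178 CPM in section 1 and 231 CPM in section 2, against 40.3 and 70.7 CPM in deeper spots. Il1b stood at 33.5 CPM in section 1 (48 UMIs, 95% exact interval 24.7 to 44.4) and 32.0 CPM in section 2 (41 UMIs, 23.0 to 43.5), against 22.7 and 23.3 CPM in deeper spots. The B and plasma cell list stood at 365 CPM in section 1 and 83.6 CPM in section 2, against 4.17 and 17.4 CPM in deeper spots. These spots also held more Gm42418 (2.94% and 3.05%, against 1.18% and 1.48% in deeper spots), more Malat1 (4297 and 4035 CPM, against 1524 and 1592 CPM) and more transcripts of the red blood cell list (752 and 855 CPM, against 208 and 315 CPM), so RNA quality and blood may contribute. Each of the levels of Saa3, Ptgs2, Il1b and the B and plasma cell list drew attention because it lies above the 2.09 CPM of section 1 or the 2.34 CPM of section 2 that a count of 0 would allow in those spots. The levels in deeper spots lie above these floors too, so passing them does not mark a level as unusual. For Il1b in section 2 the interval includes the 23.3 CPM of deeper spots.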

How the results depend on the processing

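Settings chosen only after the data were seen were the negative spots matched on depth or on region, the rim without muscle transcripts, the scores of neighbouring spots, the spots outside region 3 and the Il1b-macrophage list without Il1rn and Thbs1. Of the values that answer a comparison, 62 stayed within their limit in another setting, which was 1.5 times for counts and mostly the spread of the sections otherwise. Beyond that limit 29 moved, while 23 counts fell by more than 1.5 times and 2 rose by more than that. Of the single genes, lists and pairs of lists, 3050 stayed, 217 moved, 414 lost a call, 50 gained one and 16 changed sign. The numbers that stayed overstate stability. With 1 section left out, correlations, the score difference by distance and Moran's I of Il1b lie within the spread by construction. A single gene then counted as stayed unless it had passed and its sign changed. Where no cause is named, the cause was not tested.

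Genes higher and lower in Il1b-positive spots (257 and 118) numbered 48 and 7 with DESeq2, 1101 and 655 with no thinning, 3 and 0 with thinning to 1500 UMIs, 29 and 34 with at least 2 Il1b UMIs, 78 and 38 among macrophage-high spots, 161 and 63 with negative spots matched on depth, and 114 and 23 with negative spots matched on region. At 1500 UMIs edgeR found 377 and 432 genes at an unadjusted p under 0.05. The positive spots fall from 179 and 255 to 132 and 142 at 1500 UMIs and to 18 and 24 with at least 2 Il1b UMIs, so fewer counts stand behind these tests. Rim genes (2053 and 1519) numbered 704 and 239 with DESeq2, 1241 and 852 with a rim of distance 1, and 811 and 423 with thinning to 3000 UMIs, and 963 were lower without muscle transcripts. Without the section block, which gives up the pairing of classes within a section, 12 and 0 genes passed in the Il1b comparison (552 and 373 at an unadjusted p under 0.05) and 0 and 0 at the rim (1613 and 911), where Il1b also lost its call, and limma voom with the block called 382 and 128, and 2198 and 1292. A single section leaves no test, so leaving 1 out gives no counts.

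With negative spots matched on region, the muscle list's median was 0.041, Acta1 0.0158 and Tnnt3 0.077, where all were negative before. With at least 2 Il1b UMIs, C3 (-0.33), Cmtm7 (-1.01), Hp (-0.65), Il33 (-0.13) and Saa3 (-0.68) changed sign, and the median of all genes shifted to -0.245. Cmtm7 was at -0.0012 with thinning to 1500 UMIs, and Igkc (-0.80) and Junb (-0.10) turned negative with no thinning. At the rim, Hba-a2 was at -0.21 in thinned spots and the adipocyte median at 1.94 with no filter on low counts, a setting that shifted the median of all genes to -0.116 in the Il1b comparison and -0.101 at the rim.

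The correlation of the Il1b-macrophage and IL-1 response scores (0.181, and 0.1809 to 0.1811 with either section left out) was 0.1417 by Spearman's rho, 0.1408 given the tumour epithelium and macrophage scores, 0.171 given the neutrophil score, 0.247 with neighbouring spots, 0.1293 outside region 3, 0.1607 without Il1rn and Thbs1, 0.238 with no thinning and 0.1354 at 1500 UMIs. Outside region 3 the correlation with hypoxia was -0.0157 for the Il1b-macrophage score and -0.0497 for the IL-1 response score. That of Il1b-macrophage and endothelial scores was -0.0026 given the tumour epithelium and macrophage scores. The step difference in IL-1 response was 0.0976 from spots with the top 10% of Il1b-macrophage scores and ranged from 0.0226 to 0.0821 with 1 section left out.

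The share of variance between regions went from 8.17% to 5.85% at resolution 0.3, 8.88% with list genes kept and 6.86 to 9.08% with 1 section left out for the Il1b-macrophage score, from 12.8% to 9.72%, 15.6% and 10.8 to 15.7% for the IL-1 response score, and from 30.7% to 19.9% at resolution 0.3 and 12.4 to 32.6% with 1 section left out for hypoxia. The excess of the most hypoxic region in the IL-1 response score was 0.124 at resolution 0.3, 0.199 with list genes kept and 0.123 to 0.209 with 1 section left out, and in the Il1b-macrophage score 0.146, 0.225 and 0.162 to 0.211. Moran's I of Il1b was 0.107 with no thinning and 0.0351 to 0.0443 by section, and it has no value among genes seen in at least 20% of spots, which Il1b is not. Spearman's rho between the sections across genes was 0.698 with no thinning and 0.638 with that minimum. The lists beyond 95% of random lists numbered 13 to 18 in the Il1b comparison and 16 to 20 at the rim, and 14 to 16 and 20 with 1 section left out. Depth limits Il1b: at 3000 UMIs per spot only 18 and 24 spots hold more than 1 Il1b UMI.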

Other observations

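The test of region 3 against region 2 and all the tests of explanations in this part were chosen only after the results they concern had been seen.

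Region 3 differed from region 2 in hypoxia, endothelial and immediate early and stress genes, with no detectable difference in Il1b. Thinned counts were summed over 272 and 442 spots of region 3 and 623 and 868 of region 2, and 206 genes, those of the fixed lists and Il1r1, were tested with edgeR's quasi-likelihood test. Saa3 was higher in region 3 by a log2 fold change of 2.57 ± 0.13 (2 of 2 sections, adjusted p = 5.85e-86), Ptgs2 by 2.08 ± 0.13 (2 of 2 sections, adjusted p = 5.42e-55) and Cxcl2 by 2.96 ± 0.28 (2 of 2 sections, adjusted p = 3.93e-25). Arg1 (2.68), Il33 (2.09), S100a8 (2.28) and the cytokine gene Il6 (3.89; 2.25 in section 1 and 4.04 in section 2) were higher too. All 16 hypoxia genes tested, 8 of 9 immediate early and stress genes and 4 of 5 neutrophil genes were higher, while 11 of 12 endothelial genes, such as Plvap (-2.64), 3 of 5 pericyte genes, such as Rgs5 (-2.59), and 3 of 4 MHC class II genes were lower. Of the Il1b-macrophage list 8 of 13 were higher and 1 lower, and of the IL-1 response list 7 of 23 were higher and 4 lower. Macrophage genes went both ways. Of the C1q and Folr2 list 2 of 8 were higher, such as F13a1 (2.30), and 5 lower, such as C1qa (-0.64). Of the general macrophage list 4 of 12 were higher and 2 lower, and of the Spp1-macrophage list 5 of 10 were higher and 0 lower. Il1b differed by 0.10 ± 0.20 (95% interval -0.29 to 0.49, adjusted p = 0.668, 0.03 in section 1 and 0.11 in section 2 after TMM scaling over all genes). Without that scaling Il1b was at 42.9 CPM in region 3 and 45.5 CPM in region 2 of section 1, so the sign in section 1 depends on it. In all, 74 of the 206 genes were higher and 54 lower.

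Mast cell protease transcripts were frequent. Mcpt4 had 2390 and 2474 UMIs in the 2 sections, Mcpt2 6068 and 7008, Mcpt1 1363 and 1507 and Mcpt8 2660 and 3310. Mcpt4 was lower at the rim and in region 3 (-1.71 against region 2). Other transcripts of mast cells were scarce, with 3 and 5 UMIs for Cpa3, 13 and 15 for Tpsb2 and 9 and 12 for Cma1.

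The rise of macrophage genes in Il1b-positive spots, with a list median of 0.625, was weighed against depth, position and counting noise. With negative spots matched on depth the median was 0.592, and matched on region 0.597, so neither is likely to be the whole cause. Of 20 random choices of as many spots, 0 gave as many called genes of any kind (highest 12, against 375). Their medians for the macrophage list reached at most 0.245, below the main and both matched values. The IL-1 response list, with a median of 0.305, fell to 0.189 when matched on depth and 0.19 when matched on region, and the sections' spread of 0.149 is too wide to tell whether depth or position could account for its rise. Random choices of spots gave it medians of up to 0.205, below 0.305 but above both matched values, so counting noise stays open for it too. Which cells hold these transcripts within a spot stays open, and no biological explanation was tested for either list.

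The excess of Cxcl2, Ptgs2 and Saa3 in region 3 over region 2 was weighed against RNA quality, Il1b level and a general tie to hypoxia. Region 4 has a like share of Gm42418 (2.84% and 2.86%, against 2.36% and 2.96% in region 3), yet in sections 1 and 2 Ptgs2 was 3.11 and 4.14 times, Saa3 2.34 and 5.06 times and Cxcl2 5.97 and 2.31 times as high in region 3 (lowest lower 95% limit 1.367, from resampled spots), which argues against RNA quality as the whole cause. RNA quality may be a part, since region 4 exceeded region 2 by 2.92 times for Cxcl2 in section 2 and 1.95 times for Saa3 in section 1. The limits from resampled spots, here and below, treat spots as independent. Neighbouring spots were alike (Moran's I of Saa3 0.30 and 0.46), so these limits are probably too narrow. Il1b differed by 0.1021 with an upper limit of 0.49, below the 2.08 of Ptgs2, so the excess came without a detectable excess of Il1b transcript. Region 2 had already been seen to match region 3 in Il1b, so this outcome was known beforehand. It bears on the excess over region 2 alone, since region 1 had less Il1b, at 10.3 and 15.1 CPM. A linear tie of these genes to hypoxia across the tumour is unlikely as the whole cause. The hypoxia score kept most of its spread outside region 3 (SD 0.336 and 0.322, against 0.399 and 0.41 over all spots), and the slope on it there, corrected for the score's reliability of 0.527 and 0.516, would give at most 11.03% of the excess of any of the 3 genes over region 2 (highest upper 95% limit 25.8%, from resampled spots). A response that sets in only at the hypoxia of region 3 was not seen outside it. Of the spots there, 108 and 89 had a hypoxia score above the median of region 3. In these, Cxcl2 was at 3.09 and 0.0 CPM, Ptgs2 at 37.0 and 71.2 CPM and Saa3 at 24.7 and 30.0 CPM, each below region 2. At the reliability given above, however, many scores so high outside region 3 may be raised by noise, so such a response stays open. IL-1β protein, which transcripts do not measure, more neutrophils, whose genes were higher there too, and other signals confined to region 3 may contribute and were not tested.

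The Mcpt transcripts were weighed against mast cells and tumour epithelium as their source. Cpa3, an abundant mast cell transcript, had at most 0.202% of the UMIs of Mcpt4 (0.126% in the other section), which argues against mast cells as the source of Mcpt4. Mcpt1, Mcpt2 and Mcpt8 were not set against Cpa3, and sources other than mast cells and tumour epithelium were not tested. The correlations of Mcpt2 (0.225 and 0.199) and Mcpt4 (0.167 and 0.141) with the tumour epithelium score lay at percentile 100 among genes of like level in both sections, consistent with expression by tumour epithelium, a candidate source found and tested on the same data. For Mcpt1 and Mcpt8 the percentiles ran from 53.5 to 99.5, which leaves their source open. Reads shared among these similar genes may also contribute and were not tested.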
